A study of Drosophila melanogaster with 6 samples.

How the data were processed

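TGIRT-seq libraries of 6 samples were used, 3 of heads from mated Canton-S females 8 days old and 3 of ovaries from females 3 to 4 days old. Groups and replicate numbers were taken from the labels. The labels' protocols describe cultured S2R+ cells, RNA interference against a lacZ control, Trizol extraction, DNase treatment and ribosomal depletion with riboPOOL probes extended to 5S and 2S rRNA. They are shared text and do not describe the dissection of the tissues.

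The deposited values were estimated counts per gene, raw and not normalized, in a separate table for each tissue. The authors used cutadapt 3.4, Bowtie2 and STAR with the dm6 build, per the submitters' processing notes, which give no role or order. The counting options, strand setting and annotation were not given in the sources used here. The tables carry the name coco, that of a counter which corrects for genes nested in introns and divides multimapped reads between copies, but no header describes its use. Of the values per library, 90.8% to 95.9% were whole within 1e-09 and the rest decimal. Of whole values from 2 to 99, 82.2% to 84.2% were even in heads and 93.1% to 94.1% in ovaries, so most read pairs appear to have added 2 counts. Both tables had the same 23932 IDs, of which 23365 had a symbol and 567 did not in the Ensembl release 115 annotation of BDGP6.54 (the dm6 coordinates), from which symbols, 1-based coordinates, strands, introns and RNA classes were taken. No row was a total or an unassigned class, and 0 columns were left unmapped.

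Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, library sizes were the sums over kept genes, and TMM factors ranged from 0.946 to 1.04. Heads were compared with ovaries in all 6 libraries by glmQLFit and glmQLFTest, two-sided, without covariates, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The SE was the absolute log2 fold change over the square root of F. CPM were scaled by library size and TMM factor. Folds against a tissue at 0 in every library used a floor of 6 counts (3 read pairs) per library. Library totals ran from 15833387 to 21553143 counts. Read pairs carried no molecular identifiers, so floors cover counting error only.

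Before the data were examined, 33 gene lists were fixed: C/D box, H/ACA box and other snoRNAs, scaRNAs, C/D and H/ACA core proteins, assembly factors, RNA polymerase I and rRNA processing, ribosomal proteins, Uhg hosts, snRNAs, 7SL with RNase P and MRP RNA, nuclear tRNAs, mitochondrial protein-coding genes, histones, and markers of neurons, photoreceptors, glia, clock, olfaction, fat body, antimicrobial response, muscle, germline, piRNA pathway, meiosis, cell cycle, eggshell, yolk, hemocytes, gut, spermatheca and male or seminal tissue. The snoRNA class was taken from the pattern of the FlyBase symbol. The listed names nos, dec-1, GAR1 and NOP10 were matched to nanos, dec, Gar1 and Nop10, and don was not matched. The 29 lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and with an estimated one, adjusted over lists.

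The genes named follow a rule fixed at the same time. It takes the 8 highest and 8 lowest log2 fold changes among genes other than small structured RNAs with adjusted p under 0.05, average log2 CPM of at least 6 and no overlap of libraries between tissues. For C/D box snoRNAs it takes the 6 highest, 6 lowest (average log2 CPM of at least 4) and 4 most abundant, and for H/ACA box snoRNAs 3 of each. It also takes up to 4 of the most abundant tested members of every list and all snoRNP core proteins. Genes added later are said to be so.

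Class shares were percentages of a library's counts, compared by an exact permutation test, which cannot go below p = 0.1 for 3 against 3 libraries. Correlations of snoRNAs with hosts used 100000 permutations of host genes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these and for figures. Alternatives fixed in advance were DESeq2 1.42.0 size factors, library totals, TMM without small structured RNAs, scaling to snoRNA counts, the DESeq2 Wald test, limma-voom, no filter, at least 10 counts in 3 libraries, unrounded counts, a 2-fold threshold (glmTreat), a replicate block, leaving out each replicate, other denominators of the C/D box share, C/D box snoRNAs only, 1 value per host and an estimated correlation. Added after seeing the data were genes with no exon on the other strand, halved counts, the share without U3, H/ACA box hosts only, and 4 RNAs (Or-ACA6 to Or-ACA9) that the H/ACA name pattern leaves out.

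The tests were checked on simulated counts for the 11123 tested genes, with 200 genes changed. edgeR recovered 3 of 50 genes changed 1.5-fold, 24 of 50 at 2-fold, 40 of 50 at 4-fold and 38 of 50 at 8-fold. It called 11 of 10923 unchanged genes, 9.48% of its calls, which is above the 5% aimed for. Camera recovered a simulated 2-fold fall of H/ACA box snoRNAs and called 0 of 28 other lists. Simulated genes were drawn independently of each other, so this does not bear on lists whose genes vary together. With 200 genes changed, against 9300 called in the data, the edgeR rates need not hold there. The host test passed in 2 of 50 simulations with no relation and in 50 of 50 with a slope of 1. Results for some genes are not reported here.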

Results

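RNA was measured in heads and ovaries of mated females of the Canton-S wild-type strain of Drosophila melanogaster, with 3 libraries per tissue. Head libraries came from flies 8 days old and ovary libraries from flies 3 to 4 days old, so tissue and age differed together. The libraries were made by TGIRT-seq, in which a thermostable group II intron reverse transcriptase copies structured small RNAs, such as small nucleolar RNAs (snoRNAs) and tRNAs, together with longer RNAs after depletion of ribosomal RNA. Each library held estimated read counts for 23932 annotated genes and transposable element copies. The totals were 19272374, 21553143 and 21075852 counts in heads 1 to 3, and 20081225, 17816311 and 15833387 in ovaries 1 to 3. Counts above 0 were present for 15250, 15472 and 15569 genes in the head libraries and for 9965, 10089 and 8900 in the ovary libraries. No pair of libraries of a tissue matched within counting noise, with chi-square per degree of freedom from 9.84 to 13.5 between head libraries and from 20.3 to 31.3 between ovary libraries. Counts were halved first, so that counting of read pairs alone gives about 1. Therefore no library was treated as a copy of another. Nothing in the labels says that replicates came from separate pools of animals, so p-values measure only the spread between these samples, which may be technical. Levels are counts scaled to library size (CPM), given as mean ± SD over n = 3 libraries per tissue, and log2 fold changes are heads minus ovaries, ± SE.

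The first comparison asked which genes differed between heads and ovaries. Photoreceptor genes were prominent among the genes highest in heads. Arrestin 2 (Arr2; FBgn0000121, chromosome 3L, 8647261 to 8648936), which shuts off activated rhodopsin, was at 7089.9 ± 148 CPM in heads and at 0 in all ovary libraries, at least 21581-fold higher. Arr1 (FBgn0000120, chromosome 2L, 18078269 to 18081307), the other photoreceptor arrestin, was at least 14663-fold higher, and ninaE (FBgn0002940, chromosome 3R, 19886255 to 19888206), the major rhodopsin, at least 10832-fold. Eggshell and oocyte genes were prominent among those highest in ovaries. The chorion gene Cp36 (FBgn0000359, chromosome X, 8479319 to 8480523) was at 3494 ± 1122 CPM in ovaries and 0 in heads, at least 11631-fold higher in ovaries. The translational repressor nanos (FBgn0002962, chromosome 3R, 19157238 to 19160202) was at 2009.9 ± 64.4 CPM and 0, and yl (FBgn0004649, chromosome X, 14193214 to 14199958), the yolk protein receptor of the oocyte, was at 4364 ± 524 CPM, with 2 counts in 1 head library and 0 in the others. Bounds on folds were computed against a floor of 6 counts per library, which is 3 read pairs, and cover counting error only.

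The remaining genes named among the 8 highest in heads were ninaC (FBgn0002938, chromosome 2L, 7377702 to 7384344), a photoreceptor myosin, at 1672 ± 44.6 CPM, trp (FBgn0003861, chromosome 3R, 29914521 to 29920289), a light-activated cation channel, at 1028 ± 39.7, CG17108 (FBgn0032285, chromosome 2L, 10692940 to 10694103) at 949 ± 160.1, Ggamma30A (FBgn0267252, chromosome 2L, 9256563 to 9302494), a G protein subunit of the visual cascade, at 709 ± 6.21, and Pdh (FBgn0011693, chromosome 3L, 16353233 to 16354297), a photoreceptor dehydrogenase, at 545 ± 27.4 CPM. All 5 were at 0 in every ovary library, and 43.3% of the exonic bases of Pdh lay under exons of a gene on the other strand. The remaining genes named among the 8 lowest were the chorion genes Cp38 (FBgn0000360, chromosome X, 8481837 to 8483311) at 1714 ± 241 CPM in ovaries and Cp15 (FBgn0000355, chromosome 3L, 8728481 to 8729066) at 894 ± 161, fs(1)Ya (FBgn0000927, chromosome X, 2724286 to 2726577), a nuclear envelope protein of the early embryo, at 495 ± 77.6, Pxt (FBgn0261987, chromosome 3R, 17719454 to 17722955), a peroxidase that acts in follicle maturation, at 456 ± 46.4, and dUTPase (FBgn0250837, chromosome 2L, 11011312 to 11012135), which removes dUTP before DNA synthesis, at 333 ± 11.1 CPM. These 5 were at 0 in every head library. The exons of dUTPase were fully covered by exons on the other strand, a class of genes whose head counts are described at the end.

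Of 11123 genes tested, 9300 (83.6%) passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 5663 higher and 3637 lower in heads. At least 2-fold differences were fitted for 5146 of the higher and 2991 of the lower genes. The libraries of the tissues did not overlap for 86.6% of tested genes, where chance gives 10%. Among tested genes, 1766 were at 0 in all ovary libraries and 117 at 0 in all head libraries. The median log2 fold change of all tested genes was 0.82 under the trimmed mean of M values (TMM) scaling and ranged from 0.73 to 1.29 over the other scalings, and was 1.24 for genes with no exon on the other strand, so medians of RNA classes are also given relative to it and those of other lists are to be read against it. With tissue, age and deposited table coinciding, the comparison holds no term that separates them.

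C/D box snoRNAs, which guide 2'-O-methylation of ribosomal RNA or, as U3 and U14, its processing, went both ways. Of 112 in the table, 100 were tested: 54 were higher in heads, 18 were lower and 28 did not pass, and 53 and 18 passed when adjusted over the list alone. Higher and lower calls numbered 65 and 12 with scaling to snoRNA counts, 58 and 16 with DESeq2 size factors, and 52 and 21 with library totals. Me28S-G2703a (FBgn0082931, chromosome 2R, 14623517 to 14623607), in an intron of the non-coding host gene Uhg5, was at 80.2 ± 6.94 CPM in heads and 1.54 ± 1.23 in ovaries (5.65 ± 0.54). Me28S-A2113 (FBgn0086039, chromosome 2L, 19008611 to 19008683), in an intron of RpL30, was 44.4-fold higher in heads, at 247 ± 21.3 against 5.58 ± 1.46 CPM. In the other direction, Me18S-G1952 (FBgn0082950, chromosome 2R, 14622802 to 14622877), also in an intron of Uhg5, was 9.18-fold lower in heads, at 12.3 ± 2.32 against 113 ± 13.4 CPM.

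Other C/D box snoRNAs high in heads were U14:30Ea (4.90 ± 0.31) and U14:30Eb (4.71 ± 0.41), near-identical copies between which reads may have been divided, and Me28S-U2134b (4.03 ± 0.20) in an intron of RpL13A. The U3 copies, near-identical RNAs needed for processing of the small-subunit rRNA, were among the most abundant and all lower in heads. U3:9B (FBgn0065046, chromosome X, 10348125 to 10348337) was 3.33-fold lower, at 1319.7 ± 58.0 against 4393 ± 185 CPM, U3:54Aa fell by 0.73 on the log2 scale, and U3:54Ab was at -0.50 ± 0.10 (adjusted p = 0.0025), a call lost with DESeq2 size factors (-0.26) and with scaling to snoRNA counts (-0.028). Me18S-A1576, in an intron of Uhg2, was at 1905 ± 111 CPM in heads and 3274 ± 398 in ovaries (-0.78 ± 0.11). Me18S-G1358c was at -1.52 ± 0.39 (adjusted p = 0.0077) and Me18S-A1806 at -0.99 ± 0.14. Or-CD2 (1032 ± 148 CPM in ovaries) and Me28S-G3253 (292 ± 107 CPM) were at 0 in all heads, and both were fully covered by exons on the other strand. Counting options were not given in the sources used here, and without a stated strand setting reads of covered genes cannot be told apart from reads of the gene on the other strand.

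As a class, C/D box snoRNAs had a median log2 fold change of 0.81 and a mean of 0.67, with quartiles at -0.18 and 1.96. The median lay -0.012 from that of all tested genes, an offset that moved with the genes tested: the medians were 0.93 against 1.24 for genes with no exon on the other strand, 0.93 against 1.16 without ovaries replicate 2, and 0.98 against 0.74 with counts halved before rounding. The gene set test did not separate the class from other genes (camera adjusted p = 0.50, and adjusted p = 0.94 with an estimated correlation), and its direction was upward although the median lay slightly below that of all genes. The 3 most abundant members held 31.5% of the class's counts in heads and 49.7% in ovaries.

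**Figure D1:**
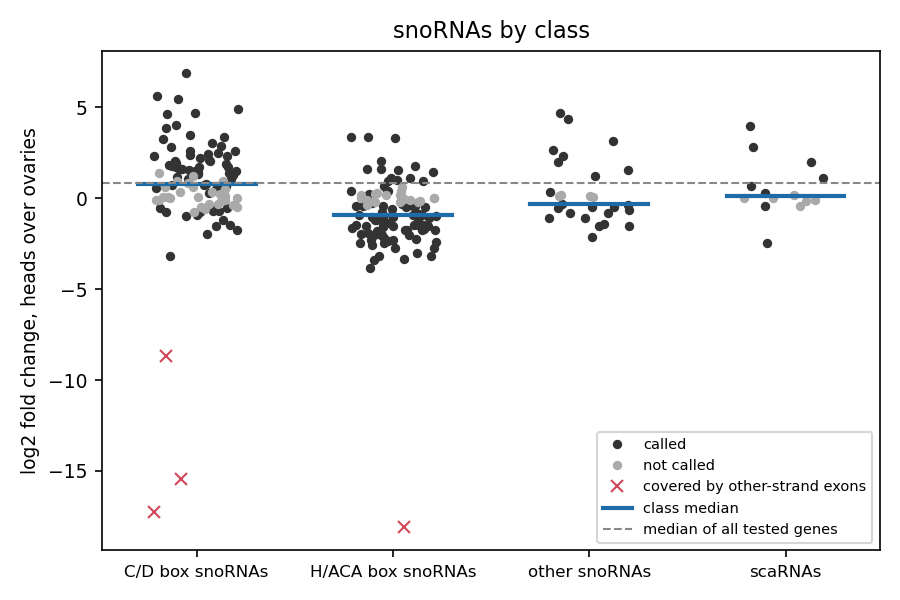
Each point is a tested snoRNA or scaRNA, placed by class on the horizontal axis and by its fitted log2 fold change, heads over ovaries, on the vertical axis; dark points passed the test, grey points did not, and crosses mark RNAs covered to at least 99% by exons on the other strand. Solid bars are class medians, 0.81 for C/D box, -0.91 for H/ACA box, -0.32 for other snoRNAs (above 0, at 0.15, when scaled to snoRNA counts) and 0.11 for scaRNAs, and the dashed line is the median of all tested genes, 0.82.

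H/ACA box snoRNAs, which guide pseudouridylation, were mostly lower in heads. Of 111 in the table, 108 were tested: 70 were lower, 19 were higher and 19 did not pass, with the same counts when adjusted over the list alone. Psi28S-3342 (FBgn0086667, chromosome X, 5524302 to 5524465) was at 2563 ± 226 CPM in heads and 6097 ± 785 in ovaries (-1.25 ± 0.12). Psi28S-2949 (-3.37 ± 0.28) and Psi18S-640a (-3.34 ± 0.23) were the lowest of those with counts in heads that the naming rule gave. Psi18S-1377d (FBgn0083048, chromosome 3R, 30207156 to 30207291), in an intron of RpS7, went the other way, at 197 ± 9.58 against 19.0 ± 6.41 CPM (3.38 ± 0.23), as did Psi18S-525k (3.31 ± 0.31) in an intron of Msp300 and Psi28S-1180 (1.77 ± 0.11).

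The most abundant member, Psi28S-2622, was at 5278 ± 353 CPM in heads and 7013 ± 659 in ovaries (-0.41 ± 0.10), but this call ended with DESeq2 size factors (-0.17) and its sign turned with scaling to snoRNA counts (0.059). Psi18S-531 did not pass (-0.078 ± 0.075, adjusted p = 0.36). Or-aca4 (FBgn0082922, chromosome 2R, 17616756 to 17616917) was at 1843 ± 146 CPM in ovaries and 0 in heads, and was fully covered by exons of genes on the other strand. The class median was -0.91, the mean -0.90, the quartiles -1.76 and 0.046, and the median lay -1.73 from that of all tested genes. The set was lower in heads than other genes by camera at the preset correlation (camera adjusted p = 1.8e-06, and adjusted p = 0.31 with an estimated correlation). Higher and lower calls numbered 28 and 60 with DESeq2 size factors, 29 and 60 with the DESeq2 Wald test, and 34 and 56 with scaling to snoRNA counts, and the median stayed below 0 under all 5 scalings. Most tested snoRNAs, 96 of 100 C/D box and 91 of 108 H/ACA box, had a decimal count in some library, and near-identical copies are uncertain as single genes.

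Of the remaining guide RNAs, 27 other snoRNAs were tested, with 9 higher and 14 lower in heads, also when adjusted over the list alone. Among these, hts-a was at 610.0 ± 36.8 against 262 ± 32.2 CPM and Tudor-SN-a at 452 ± 26.1 against 785 ± 80.2 CPM. Their median was -0.32, which lay -1.14 from that of all genes, but their mean 0.35, and the median turned to 0.15 with scaling to snoRNA counts. The set test did not pass (camera adjusted p = 0.13, and adjusted p = 0.49 with an estimated correlation). Of 14 tested small Cajal body RNAs (scaRNAs), which guide modification of spliceosomal RNAs, 6 were higher and 2 lower, and 5 and 2 passed when adjusted over the list alone. scaRNA:MeU5-C46 was 3.99-fold higher in heads (1.99 ± 0.13) and scaRNA:MeU2-G25 2.14-fold (1.10 ± 0.089). The scaRNA median was 0.11, which lay -0.71 from that of all genes, while camera's direction was upward (camera adjusted p = 0.88, and adjusted p = 0.94 with an estimated correlation).

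The share of each RNA class among a library's counts needs no scaling factor. C/D box snoRNAs took 2.06% ± 0.0358 of counts in heads and 2.35% ± 0.152 in ovaries, a difference of -0.293 percentage points, with every head library below every ovary library. The sign of this difference turned without tRNA, snRNA, 7SL, RNase P, RNase MRP and rRNA in the denominator (0.0355 points), and without rRNA alone it was -0.645 points. The 3 U3 copies, set apart after seeing the data, held 0.527% ± 0.0281 in heads and 1.09% ± 0.0450 in ovaries, a gap larger than that of the class, so by subtraction the rest of the class differed by 0.267 points. H/ACA box snoRNAs took 3.65% ± 0.274 of counts in heads and 6.03% ± 0.236 in ovaries. Mitochondrial tRNAs took 17.0% ± 1.32 of counts in heads and 4.00% ± 0.479 in ovaries, nuclear tRNAs 19.8% ± 1.14 of counts in heads and 12.0% ± 1.46 in ovaries, and mitochondrial rRNAs 4.06% ± 0.647 of counts in heads and 15.5% ± 2.05 in ovaries. Transposable elements took 0.351% ± 0.0104 of counts in heads and 0.0451% ± 0.00207 in ovaries, and nuclear protein-coding genes 43.3% ± 1.73 of counts in heads and 50.1% ± 0.425 in ovaries. The exact two-sided permutation test gave p = 0.1 for each of 16 classes (0.1 after Benjamini-Hochberg adjustment), the smallest that 3 against 3 libraries allow, so no class could pass 0.05.

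**Figure D2:**
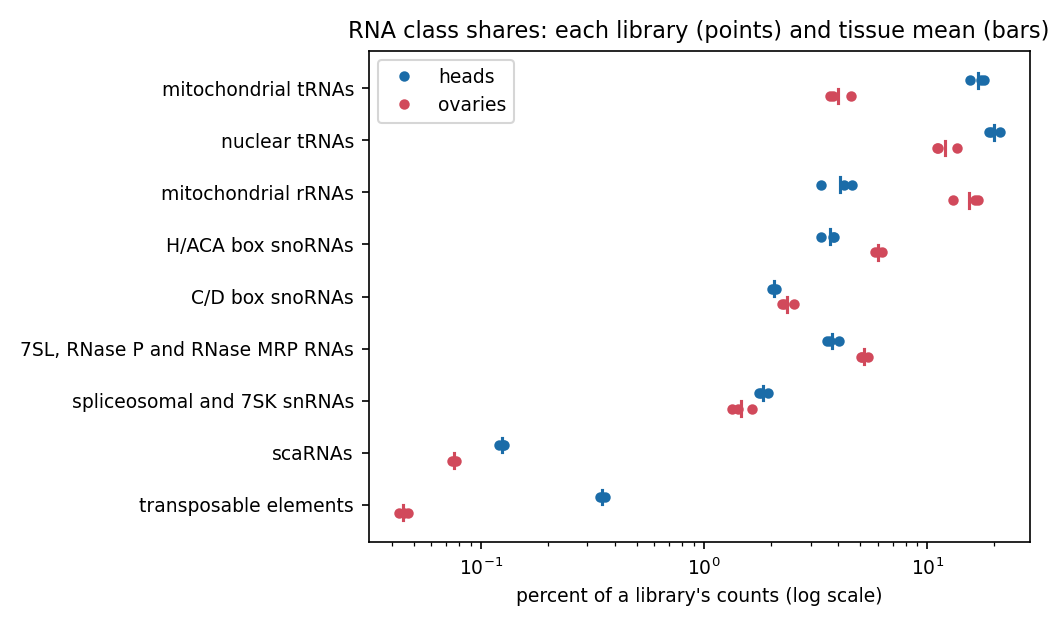
Points are the 3 head and 3 ovary libraries and short bars the tissue means; the horizontal axis is the percent of a library's counts on a log scale and the vertical axis lists 9 RNA classes. Head and ovary points do not overlap in any class shown, with mitochondrial tRNAs at 17.0% in heads and 4.00% in ovaries and C/D box snoRNAs at 2.06% and 2.35%, a difference whose sign depended on the denominator.

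Genes for the proteins that bind snoRNAs were lower in heads. All 4 C/D box core proteins fell, also when adjusted over the list alone. Fib (FBgn0003062, chromosome 2R, 23072909 to 23074725), the methyltransferase fibrillarin, was at 22.2 ± 2.21 CPM in heads and 596 ± 44.0 in ovaries, 26.8-fold lower (-4.74 ± 0.12), and hoip, which binds the kink-turn of the RNA, was 37.7-fold lower (-5.24 ± 0.12). Nop56 was at -2.69 ± 0.12 and nop5 at -1.80 ± 0.15. Of the H/ACA box core proteins, 3 of 4 fell, with the same count over the list alone: Nop60B, the pseudouridine synthase (-2.11 ± 0.19), NHP2 (-2.77 ± 0.19) and Nop10 (-2.50 ± 0.20), of which 31.6% lay under exons on the other strand. Only 2 of the 4 had no exonic base under such exons, and 1 of these fell. Gar1 did not pass (-0.64 ± 0.37, adjusted p = 0.15), though it did without ovaries replicate 2 (-0.84). The medians were -3.72 (camera adjusted p = 0.0069, and adjusted p = 0.27 with an estimated correlation) and -2.31 (camera adjusted p = 0.035, and adjusted p = 0.21 with an estimated correlation).

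Among 5 assembly factors, the ATPases pont (-4.04 ± 0.10) and rept (-3.39 ± 0.16) and Pih1D1 (-2.05 ± 0.11) fell, spag did not pass (-0.25 ± 0.45), and Nufip was higher, at 0.958 ± 0.543 CPM in heads and 0 in ovaries, at least 2.91-fold. Nufip had exonic bases under exons on the other strand, which the other 4 did not. Their median was -2.05 and their mean -0.50 (camera adjusted p = 0.090, and adjusted p = 0.27 with an estimated correlation). This list passed for genes with no exon on the other strand (adjusted p = 0.016) and with halved counts (0.038), in a range from 0.016 to 0.11 over 11 alternatives. Of 19 genes of RNA polymerase I and rRNA processing, 13 fell, 3 were higher and 3 did not pass, with the same counts over the list alone. RIOK1, a kinase of small-subunit maturation, was at -4.01 ± 0.12, nclb at -3.41 ± 0.14 and the nucleolar GTPase Ns1 at -2.95 ± 0.10. The higher 3 were Non1 (0.61 ± 0.12), pes (1.54 ± 0.14) and Nop17l (2.10 ± 0.24). The list median was -2.13 (camera adjusted p = 0.0011, and adjusted p = 0.11 with an estimated correlation). Of 83 ribosomal protein genes tested, 43 fell and 30 were higher, also over the list alone. RpLP2 was at -2.26 ± 0.092, RpL27A at -2.17 ± 0.087, RpL5 at -1.22 ± 0.077 and RpLP0 at -1.22 ± 0.080. The list median was -0.41, and 0.062 with scaling to snoRNA counts (camera adjusted p = 0.014, and adjusted p = 0.38 with an estimated correlation). The ribosomal protein call also ended with counts halved before rounding (adjusted p = 0.055, in a range from 4.7e-04 to 0.055 over 11 alternatives). Nufip, pes and Nop17l were chosen after their values were seen.

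Most fly snoRNAs lie in introns, and the next comparison asked whether their changes followed those of their hosts. In the annotation, 100 of 112 C/D box and 105 of 111 H/ACA box snoRNAs lay in an intron of a gene on the same strand. Some genes hosting several snoRNAs held members that differed widely. Others did not, such as Uhg3, whose 3 snoRNAs ran from -0.57 to -0.32. In Uhg5, which did not pass (-0.58 ± 0.32), 11 C/D box snoRNAs ran from -3.20 (Me18S-G1952) to 5.65 (Me28S-G2703a). In Arpc2, a subunit of the actin-nucleating complex at -3.79 ± 0.15, 17 H/ACA box snoRNAs had a median of -1.76 and ran from -3.84 to 2.02. They were the lettered series Psi18S-525a to Psi18S-525j and Psi18S-640a to Psi18S-640g. Reads may have been divided between members of a series, so this range may partly reflect their assignment. Across 190 snoRNAs in 55 host genes, Spearman's correlation of the log2 fold changes was 0.155 (p = 0.30, permutation of host genes) and Pearson's 0.194 (p = 0.073), so neither passed. These are correlations across genes, which are not independent replicates. Of 6 tested Uhg genes, non-coding hosts named for the snoRNAs in their introns, none was higher and 3 were lower, also over the list alone, among them Uhg2 (-2.50 ± 0.27) and Uhg4 (-1.97 ± 0.17, 26.9% under exons on the other strand). Uhg1 was at 0.12 ± 0.28. The Uhg median was -1.15 (camera adjusted p = 0.073, and adjusted p = 0.27 with an estimated correlation), and the list passed without ovaries replicate 1 (adjusted p = 0.039) and with the replicate block (0.043, in a range from 0.039 to 0.17 over 11 alternatives).

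**Figure D3:**
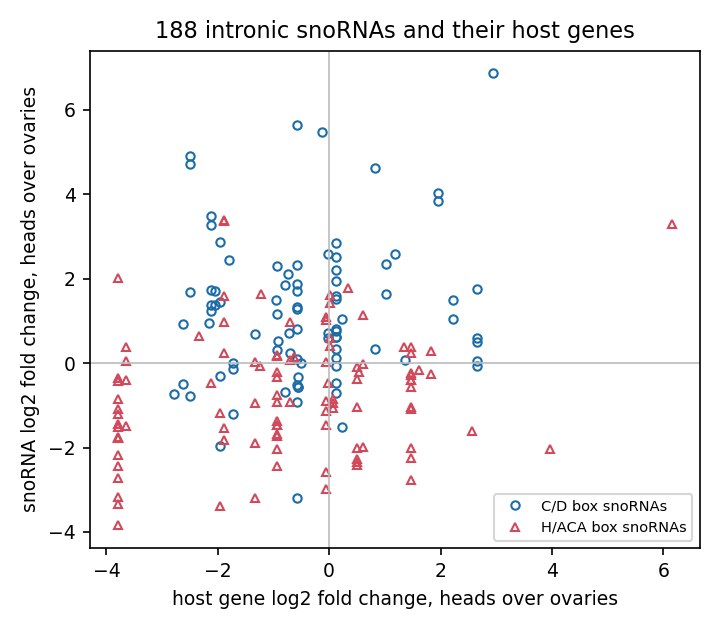
Each of 188 symbols is an intronic snoRNA, circles for C/D box and triangles for H/ACA box, with the log2 fold change of its host gene on the horizontal axis and its own on the vertical axis, both heads over ovaries. The 2 snoRNAs covered by exons on the other strand are left out of the plot, and over all 190 Spearman's correlation was 0.155.

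Lists of marker genes for cell types of the head were higher there. All 18 neuronal genes were higher in heads, including futsch, a microtubule-binding protein of axons, at 589 ± 27.4 against 0.550 ± 0.498 CPM (9.99 ± 0.47), and the synaptic genes Syt1, cpx and VGlut, at 0 in ovaries and at least 1017-, 836- and 684-fold higher. The neuronal median was 13.25, or 8.70 with the 11 genes at 0 in ovaries set to their bound (camera adjusted p = 4.6e-06, and adjusted p = 0.21 with an estimated correlation). Of 19 photoreceptor genes, 18 were higher and rdgB did not pass (-0.19 ± 0.10), with a median of 13.99, or 10.45 at the bound for 10 genes (camera adjusted p = 5.3e-06, and adjusted p = 0.19 with an estimated correlation). All 8 glial genes were higher, among them the glutamate transporter Eaat1 (6.41 ± 0.18), Gs2, glutamine synthetase (9.09 ± 0.43), nrv2 (5.34 ± 0.24) and the astrocyte gene alrm (8.70 ± 0.43), with a median of 5.88 (camera adjusted p = 0.017, and adjusted p = 0.27 with an estimated correlation). All 14 muscle genes were higher, such as the myosin heavy chain Mhc (4.98 ± 0.14), Act57B (4.90 ± 0.11) and sls (7.20 ± 0.16), with a median of 4.95 (camera adjusted p = 0.0021, and adjusted p = 0.11 with an estimated correlation). The counts of these lists were the same when adjusted over each list alone.

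Smaller head lists went the same way in their counts but did not pass the set test. Of 8 circadian clock genes, 7 were higher, such as the photoreceptor protein cry (3.90 ± 0.22) and Pdp1 (3.67 ± 0.13), and cyc was lower (-1.16 ± 0.26; list median 3.38, camera adjusted p = 0.090, and adjusted p = 0.32 with an estimated correlation). All 4 tested olfactory genes were higher, among them Obp56d, at 143 ± 6.02 CPM in heads with 2 counts in 1 ovary library and 0 in the others, and Obp19d (7.18 ± 0.75), with a median of 9.73, or 5.70 at the bound (camera adjusted p = 0.073, and adjusted p = 0.29 with an estimated correlation). Without heads replicate 3 the olfactory list passed (adjusted p = 0.048, in a range from 0.048 to 0.107 over 11 alternatives). Fat body genes were higher for 6 of 7, with the lipoprotein apolpp at 16168 ± 1549 against 42.4 ± 20.9 CPM (8.58 ± 0.45) and the fatty acid synthase FASN1 at 5.55 ± 0.24, and a median of 7.10 (camera adjusted p = 0.097, and adjusted p = 0.38 with an estimated correlation). The 3 yolk protein genes were higher in heads, Yp1 at 6.56 ± 0.24 with 54.3% under exons on the other strand, Yp2 at 4.29 ± 0.17 and Yp3 at 5.49 ± 0.28, with a median of 5.49 (camera adjusted p = 0.090, and adjusted p = 0.46 with an estimated correlation). All 5 hemocyte genes were higher, including Hml (8.79 ± 0.22) and Pxn (4.13 ± 0.44), with a median of 6.998 (camera adjusted p = 0.073, and adjusted p = 0.27 with an estimated correlation). Of 6 antimicrobial peptide genes, 3 were higher, among them Mtk, at least 29.0-fold, and AttC (3.29 ± 1.14, adjusted p = 0.027), which lost its call without heads replicate 1 (3.41), 2 (3.38) or 3 (3.08). The peptide median was 2.52 (camera adjusted p = 0.50, and adjusted p = 0.56 with an estimated correlation). Counts adjusted over these lists alone were the same.

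Ovary lists were lower in heads. Of 14 germline and oocyte genes, 13 were lower, among them bru1 (-3.96 ± 0.14) and orb (-4.04 ± 0.11), RNA-binding proteins of the oocyte, the transcription factor ovo (-4.38 ± 0.17), and nanos. The exception was grk, a ligand secreted by the oocyte, whose counts were higher in heads, at 3.41 ± 1.06 against 0.169 ± 0.151 CPM (4.22 ± 0.73), with 12.3% of its exonic bases under exons on the other strand. Its mean ovary level lay below the floor of 6 counts per library. Whether its reads went to another gene, or reads of the other strand were added in heads, was not tested, so this call is uncertain. The germline median was -7.28, or -5.47 with 4 genes at their bound (camera adjusted p = 5.3e-06, and adjusted p = 0.11 with an estimated correlation). Of 22 piRNA pathway genes, which silence transposable elements in the gonad, 21 were lower and none higher, such as vas (-9.24 ± 0.40), shu (-7.67 ± 0.35), aub (-6.68 ± 0.20) and spn-E (-5.81 ± 0.29), with a median of -5.39 (camera adjusted p = 1.1e-06, and adjusted p = 0.042 with an estimated correlation). All 23 cell cycle and DNA replication genes were lower, including the kinase polo (-10.57 ± 0.14), the helicase subunit Mcm5 (-9.91 ± 0.27) and CycB (-9.65 ± 0.33), with a median of -6.65, or -5.99 at the bound for 3 genes (camera adjusted p = 6.1e-10, and adjusted p = 0.040 with an estimated correlation). All 19 eggshell genes of follicle cells were lower, among them Cp36, Cp38, Cp15 and Cp18 (-10.38 ± 0.37), with a median of -11.50, or -8.98 at the bound for 9 genes (camera adjusted p = 7.7e-10, and adjusted p = 0.040 with an estimated correlation). Of 7 meiosis genes, 5 were lower, such as nod (-5.91 ± 0.10) and mtrm (-5.08 ± 0.29), mei-W68 was higher (2.001 ± 0.52) and c(2)M did not pass (0.71 ± 0.59). The meiosis median was -3.15, or -2.52 at the bound for 1 gene (camera adjusted p = 0.023, and adjusted p = 0.21 with an estimated correlation), and the call ended with genes that had no exon on the other strand (adjusted p = 0.057, in a range from 0.013 to 0.057 over 11 alternatives). Counts over each of these lists alone were the same, and grk, mei-W68, rdgB and c(2)M were chosen after their values were seen. Of 29 lists with at least 3 tested members, camera called 14 at the preset correlation, 4 higher and 10 lower in heads, and 3 with an estimated correlation, those of the cell cycle, eggshell and piRNA genes. Splits of the libraries that mixed the tissues gave 11 to 14 called lists at the preset correlation and 0 called genes.

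Other RNA families gave mixed results. Of 31 spliceosomal and 7SK RNAs, 10 were higher and 14 lower, and 9 and 14 over the list alone. U2:34ABb was 5.85-fold higher in heads, at 3701 ± 315 against 632 ± 86.5 CPM, and U1:95Cb 2.85-fold. The median was -0.084, -0.90 from that of all genes, and the mean -1.70, and the median turned to 0.38 with scaling to snoRNA counts (camera adjusted p = 0.053, and adjusted p = 0.49 with an estimated correlation). This list passed without heads replicate 2 (adjusted p = 0.045) or 3 (0.043), without ovaries replicate 1 (0.037), 2 (0.027) or 3 (0.041), with DESeq2 size factors (0.049), with the replicate block (0.048) and for genes with no exon on the other strand (0.044), in a range from 0.027 to 0.086 over 11 alternatives. Of 289 nuclear tRNA genes, 142 were higher and 45 lower, and 141 and 42 over the list alone, with tRNA:Glu-CTC-1-1 at 1.75 ± 0.12 and tRNA:Arg-CCT-1-1 at 1.32 ± 0.11. Their median was 0.54, -0.28 from that of all genes, while camera's direction was upward (camera adjusted p = 0.65, and adjusted p = 0.94 with an estimated correlation). Copies of a tRNA share sequence, so single tRNA genes are uncertain. The signal recognition particle RNA 7SLRNA:CR42652, which has a second copy in 7SLRNA:CR32864 (0.072 ± 0.095, adjusted p = 0.50), fell (-1.13 ± 0.13), and RNase P RNA (0.79 ± 0.081) and RNase MRP RNA (0.76 ± 0.13) were higher, in a list of 4 with 2 higher and 1 lower, also over the list alone (median 0.42, -0.40 from all genes, with camera's direction upward; camera adjusted p = 0.97, and adjusted p = 0.98 with an estimated correlation). Of 13 mitochondrial protein-coding genes, 7 were higher and 4 lower, also over the list alone, with mt:CoI at 2.61 ± 0.10 and mt:ND1 at -0.66 ± 0.12, whose call ended with scaling to snoRNA counts (-0.19). Their median was 0.45, -0.37 from all genes, with camera's direction upward (camera adjusted p = 0.85, and adjusted p = 0.94 with an estimated correlation).

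Markers of material other than heads and ovaries were near the floor, with exceptions. The 8 gut protease genes, none of them tested, summed to 81.5 CPM in heads replicate 1, 0 in replicate 2, 0.636 in replicate 3 and 0 in the ovaries. Without heads replicate 1 edgeR called 8986 genes, against 9300 with it. The 2 spermathecal genes, not tested, held 4 counts in all heads together and 26 in all ovaries. Of the male and seminal list, 2 genes were tested and both were higher in heads, also over the list alone: the dosage compensation RNA roX1, at 4.47 ± 0.148 against 0.0342 ± 0.0297 CPM, and the seminal protein Acp36DE, at least 4.89-fold. The 111 replication-dependent histone genes summed to 0.953 ± 0.386 CPM in heads and 12.2 ± 2.68 CPM in ovaries, and both tested members fell, also over the list alone (His2B:CG33868, -4.14 ± 0.39; His2B:CG17949, -3.63 ± 0.65).

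Genes under exons of the other strand differed from the rest in their head counts. Among genes with an ovary mean of at least 10 counts, 43 of 44 covered to at least 99% by such exons were at 0 in all 3 heads (97.7%), against 89 of 5242 genes with no overlap (1.70%; Fisher's exact p = 2.8e-71, two-sided). The exception was Spt-I, covered to 99.5%, at 0.997 ± 0.170 CPM in heads and 18.3 ± 4.23 in ovaries. The share was 0.615% (16 of 2601) below 50% coverage and 4.91% (8 of 163) from 50% to under 99%. The median log2 fold change of tested protein-coding genes fell from 1.03 with no overlap to -0.10, -1.50 and -10.88 in these classes of rising coverage. The covered genes included 3 C/D box snoRNAs, 1 H/ACA box snoRNA, 19 protein-coding genes, 3 tRNAs, 13 transposable elements and the spliceosomal U2:34ABc, at 1494 ± 219 CPM in ovaries and 0 in heads. The coverage classes, Spt-I and U2:34ABc were chosen after seeing the data. Of tested genes, 31.2% had some exonic base under an exon on the other strand. For the genes with none, the p-values of the main fit were adjusted again over these genes alone, without a new filter or fit. By these, 6432 of 7609 tested passed, including 52 higher and 15 lower of 95 C/D box and 19 higher and 69 lower of 107 H/ACA box snoRNAs.

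**Figure D4:**
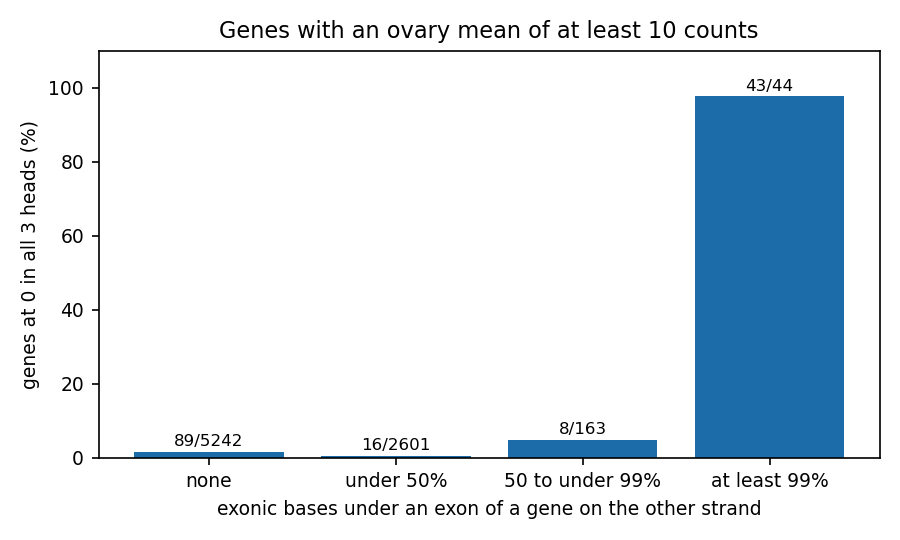
Bars give the percent of genes with an ovary mean of at least 10 counts that were at 0 in all 3 head libraries, by the share of exonic bases under an exon of a gene on the other strand on the horizontal axis. The numbers above the bars are genes at 0 over genes in the class, 43 of 44 at a coverage of at least 99% and 89 of 5242 with none.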

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

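Genes without exons on the other strand, halved counts, the share without U3, H/ACA hosts alone and the added H/ACA members were chosen after seeing the data. Of the values for whole comparisons, 105 were held to be the same. For counts of calls this meant within 1.5-fold of the main count, and the other values kept their sign. By this rule 48 C/D box calls with the 2-fold test, against 72, were the same. Adding Or-ACA6 to Or-ACA9 left 108 tested H/ACA box snoRNAs and 89 calls. H/ACA box calls were 53 instead of 89 with a test against 2-fold, which asks for larger changes, and camera called 3 lists instead of 14 with an estimated correlation, for which the cause was not tested. The C/D box share difference of -0.293 points was -0.645 without rRNA in the denominator, 0.0355 without tRNA, snRNA, 7SL, RNase P, RNase MRP and rRNA, and 0.267 without U3, by subtraction. Scaling to snoRNA counts raised the log2 fold changes of all tested genes by 0.21 to 0.50, and by that shift the sign turned for Psi28S-2622 (0.059), Psi18S-531 (0.39), scaRNA:PsiU5-44 (0.31) and mt:Cyt-b (0.41). With the DESeq2 Wald test it turned for Psi18S-531 (0.16). That setting used DESeq2 size factors, and its all-gene median was 1.06 against 0.82 in the main fit. The changes with the denominators follow from the shares removed. Mitochondrial rRNAs took 4.06% of head and 15.5% of ovary counts. Mitochondrial tRNAs took 17.0% of head and 4.00% of ovary counts, and nuclear tRNAs 19.8% and 12.0%. Of values for single named genes, 2651 were the same, 21 gained and 31 lost the call, and 5 reversed. Leaving out each replicate gave 8975 to 10064 genes, 69 to 74 C/D box and 83 to 90 H/ACA box calls, C/D box medians of 0.68 to 0.94, 14 to 16 lists, host correlations of 0.148 to 0.166 and share differences of -0.348 to -0.206 points. Same-numbered replicates did not deviate together (correlations -0.0137, -0.00492 and 0.00507), which gives no sign that the numbers pair the samples. Different tissues can share a batch without deviating together, so pairing is not excluded, and the labels do not state it. With the replicate number as a block, edgeR called 8659 genes, 71 C/D box and 87 H/ACA box snoRNAs, camera 16 lists, the C/D box median was 0.89 and the host correlation 0.156, and among named genes His2B:CG17949 alone lost its call. Of the 14 lists called, 12 stayed called in every setting in which they were tested other than the estimated correlation, the exceptions being ribosomal proteins with halved counts and meiosis without genes under other-strand exons. Other settings gave 7366 (2-fold) to 11025 genes (no filter, 17953 tested), and host correlations from 0.0808 to 0.169. Simulated 1.5-fold changes were recovered for 3 of 50 genes, a rate that need not hold for data in which far more genes differed.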

Other observations

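The tests in this part, apart from the splits of the libraries for the C/D box median and for the host correlation, were chosen after the results they bear on had been seen. Mitochondrial tRNAs and rRNAs changed in opposite directions, and mitochondrial protein-coding genes went both ways. These genes lie on both strands of the mitochondrial genome. Reads of the other strand were not measured, so the unstated strand setting may bear on these values. All 22 mitochondrial tRNAs were higher in heads by edgeR, with a median log2 fold change of 2.14, from mt:tRNA:Asp-GTC (2.66-fold) to mt:tRNA:Phe-GAA, at 1539 ± 202 against 130.2 ± 24.7 CPM (11.8-fold). The mitochondrial rRNAs were lower, mt:srRNA 11.7-fold (-3.55 ± 0.18) and mt:lrRNA 2.75-fold (-1.46 ± 0.17), in libraries depleted of rRNA. Of the protein-coding genes, mt:CoIII (4.34 ± 0.15), mt:CoI (2.61 ± 0.10), mt:ATPase6 (2.60 ± 0.30) and mt:CoII (1.82 ± 0.15), subunits of cytochrome c oxidase and ATP synthase, were higher, and the complex I subunits mt:ND2 (-1.04 ± 0.17), mt:ND3 (-1.01 ± 0.16), mt:ND6 (-0.75 ± 0.23) and mt:ND1 (-0.66 ± 0.12) were lower. Complex I did not move as a whole, since its subunits mt:ND4 (0.45 ± 0.12) and mt:ND4L (0.49 ± 0.15) were higher and mt:ND5 did not pass (0.21 ± 0.11). Nuclear tRNAs summed by anticodon on TMM-scaled CPM were higher in every head library than in every ovary library for 37 of 45 families, led by Arg-TCG (5.24-fold), and lower for 1, Asp-GTC (a ratio of 0.506), where chance gives 10% without overlap. Of all tested genes, 86.6% had no overlap between tissues, and the median of nuclear tRNA genes lay -0.28 from that of all genes. The family counts therefore do not set tRNAs apart from other genes.

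Variants of spliceosomal RNAs differed by tissue. The Sm-class RNA snRNA:LU was 124-fold higher in ovaries, at 913 ± 50.7 against 7.35 ± 1.03 CPM, as were U5:14B (18.0-fold) and U2:14B (11.0-fold), while U2:34ABb (5.85-fold) and 7SKa (7.60-fold), the RNA that holds back the elongation factor P-TEFb, were higher in heads. Copies of a snRNA share sequence, so the split between variants is uncertain. Of the scaRNAs, MeU2-48 (3.96 ± 0.12) and MeU4-A65 (2.80 ± 0.13) were higher in heads and PsiU2-55 (-2.44 ± 0.16) lower. The snRNAs, scaRNAs and mitochondrial genes of these paragraphs were chosen after their values were seen.

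Covered genes at 0 in heads formed the first pattern weighed. Lower depth in heads cannot account for it, since head totals were 1.15 times ovary totals, and lower expression alone is argued against by the excess over genes with no overlap (Fisher's exact p = 2.8e-71). The 97.7% of covered genes at 0 is consistent with head reads having been counted without strand, with reads under exons of both strands set aside, while ovary reads were counted by strand. This is a hypothesis, since the counting options were not given. Under it, 31.2% of tested genes had some bases where head reads may have been set aside. Counting without strand would also add reads of the other strand to genes with no such overlap. These reads were not measured, so genes with no exon on the other strand are not shown to be free of the difference. Whether tissue or age adds to it was not tested.

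Lower H/ACA box snoRNAs in heads formed the second pattern. The scaling is argued against as the whole cause, because the highest class median over 5 scalings was -0.45. A fall of core proteins that would set both classes predicts a C/D box median at or below that of H/ACA box snoRNAs. The C/D box median lay above it instead, by 1.84 among members with no exon on the other strand. Among all members it lay above by 1.72. The rule asked for a gap over the C/D box SD in both sets. That SD was 1.77 and 3.15, the latter widened by covered members, so this cause cannot be told apart by the rule. The SD is a spread between members and not the error of a median, and core proteins were measured as RNA only. RNA length cannot be told apart either: against 29 other small RNAs of 120 to 160 nt, 103 H/ACA box snoRNAs were lower by a median difference of -1.02 (permutation p = 0.024), but the 95% bootstrap interval ran from -1.62 to 0.00074. The 29 were other snoRNAs, C/D box snoRNAs, scaRNAs and snRNAs. They include scaRNAs with Psi names like those of H/ACA box snoRNAs, so the set is not free of that kind. Tissue and age stay open as untested, and the set test does not pass with an estimated correlation (adjusted p = 0.31).

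Transposable elements formed the third pattern, with 522 of 604 tested copies higher in heads and 25 lower, and 53 of 56 families with a summed mean of at least 10 CPM higher in every head library and 1 lower in every one (118 and 6 of all 155 families). springer was at 364 ± 13.5 CPM against 2.26 ± 1.04 CPM, Stalker2 at 337 ± 17.2 CPM against 0.907 ± 1.08 CPM and copia at 234 ± 41.4 CPM against 12.7 ± 2.76 CPM, heads against ovaries. Counting without strand adds the reads of the other strand. Elements not wholly inside a gene had a summed CPM 5.40 times as high in heads, and this ratio was 13.3 in same-strand and 17.1 in opposite-strand genes. Reads on the other strand of the elements were not measured. These ratios therefore cannot decide whether such counting was a part or the whole of the cause. Division of multimapped reads between copies keeps family sums and is argued against by their median ratio of 9.99 (95% bootstrap interval 7.35 to 14.6). Tested elements were at 22.7 times the level of histone and eggshell genes in heads (1.19 ± 0.0362 against 0.0524 ± 0.00646 CPM per kb). This cannot decide on carried-over genomic DNA. The elements had passed the expression filter, while the histone and eggshell genes were taken whether tested or not. A candidate explanation is a difference between tissues or ages, and heads also had lower piRNA pathway genes, but this was not tested.

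The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 9300 genes, 72 C/D box and 89 H/ACA box snoRNAs, and the highest other split called 0 of each; in each case 1 split, the real one, gave a result as large. For gene lists called by camera, the real split gave 14 and the highest other split also 14, so 2 splits gave as many, and the lowest gave 11. Mixed splits keep part of the difference between tissues, and camera ranks genes against each other, so these counts do not tell chance from tissue. The C/D box median was 0.81 in the real split and at most 0.46 in size in the others, with 1 split as large. The host correlation was 0.155 in the real split and 0.192 in the highest other, with 4 splits as large.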
